A study of Homo sapiens with 10 samples.

How the data were processed

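RNA from 4 human myeloid cell lines was measured on 10 single-colour oligonucleotide arrays. The lines were HL60, an acute myeloid leukaemia line, K562, a chronic myeloid leukaemia line, and MDSL and SKM1, which derive from myelodysplastic disease. Each line gave 1 control array and 1 array after OR21, the compound OR-2100 that the series describes as a hypomethylating agent. The other 2 arrays came from HL60 derivatives that the labels call AZA resistant and OR21 resistant, grown without treatment. Per the labels, treatment lasted 96 hours, at 500 nM in HL60 and K562 and at 100 nM in MDSL and SKM1. Total RNA was extracted with a Direct-zol kit and labelled with biotin, per the labels.

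The deposited values were linear intensities per probe set, from 4.25 to 405294. The software, background correction and normalization behind them were not given in the sources used here. The quartiles of the 10 arrays lay close together, so the values were treated as already normalized between arrays and were put on the log2 scale with no pseudocount. The analysis plan had left the scale open. Array medians over all genes lay between 6.63 and 7.05 log2. Intensities give no read depth, so the number of arrays limits the precision.

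The value table held 24351 rows, of which 20893 were gene probe sets, 555 were unmapped transcript probe sets and the rest were controls. A platform annotation table gave 1 gene symbol to 17709 probe sets and several symbols to 0. It did not list 6642 rows, 3739 of them gene or transcript probe sets, which are unnamed here. Entrez identifiers were looked up in a RefSeq gene table, which updated 0 symbols. For the 20 genes with more than 1 probe set, the probe set with the highest mean over the 10 arrays was kept, which left 17687 genes. No filter on dim genes was applied. 0 columns of the table belonged to no sample. The chromosome of a probe set was read from its name, and other genomic positions were not used, because no genome build was given in the sources used here.

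The response to OR21 was tested over the 4 lines with limma 3.58.1 in R 4.3.3. The fit by lmFit and eBayes used the 8 arrays of treated and control cells, the cell line as a block, two-sided tests and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. Treated and control arrays of 1 line came from the same line, so the line was the pair and the only replicate. No label says that arrays came from separate cultures. The p-values rest on the spread of the response between lines, in which dose, disease, line and array noise are mixed. By eBayes, each gene's spread was also drawn toward that of all genes, with 3.49 prior and 3 residual degrees of freedom. The difference between lines at 500 nM and at 100 nM was tested as an interaction in the same kind of fit. Genes moved at least 2-fold the same way in all 4 lines were also counted, without a test. Comparisons of single lines and of the resistant derivatives had 1 array per condition. They are given as sizes with no p-value and no replicate check, and genes moved at least 2-fold were counted.

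Gene lists were fixed before the data were examined, 26 of pathways and lineages and 5 of markers of other cell types. They were tested over the 4 lines with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 31 lists. For single comparisons, the median of a list was placed among 10000 random lists of the same size, drawn from 20 classes of mean expression. This percentile describes the arrays and is not a test.

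Named genes followed a rule set before the data were examined. Over the 4 lines it took the 14 largest rises and 10 largest falls past the threshold with 1 sign in all lines. Free places went to the largest mean changes among genes moved at least 2-fold in all 4 lines, which are given as not past the test. Each single comparison gave the 10 largest differences each way among genes whose higher value was at or above the array's median. With no gene past the threshold, the dose comparison gave 4 genes each way, chosen where both lines of 1 dose lay above both of the other. Each list gave up to 4 members. DNMT1, DNMT3A, DNMT3B, DCK, CDA, SLC29A1, UCK1, SAMHD1, CDKN1A, CDKN2B and MPO were always included.

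The steps were tested on simulated data. Over 17687 simulated genes with the fitted spread, the fit over 4 lines called 19 of 100 genes changed by 1 log2 unit, 95 of 100 changed by 2 units, and 9 unchanged genes. For the dose comparison it called 16 of 100 genes that differed by 2 log2 units, 93 of 100 that differed by 4, and 11 unchanged genes. In both simulations a changed gene had the same change in every line concerned. These shares therefore do not give the recovery of changes whose size varies between lines.

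Alternatives were quantile normalization, centring each array on its median, a fit with no cell line block, leaving out genes under the 30th percentile of mean level, the mean of a gene's probe sets, eBayes with an intensity trend and robust estimation, other fold sizes, and leaving out each line. Scaling to the hybridisation spikes, and leaving out lines in the 2-fold count, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.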

Results

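The 10 arrays covered control and OR21-treated HL60, MDSL, SKM1 and K562 cells, 1 array each, and 2 untreated resistant HL60 derivatives. Gene medians lay between 6.63 and 7.05 log2 on the 10 arrays. The array of OR21-treated HL60 stood apart in its hybridisation spikes, at a mean of 11.71 log2 against 10.85 to 11.10 on the other 9 arrays. Its polyadenylated spikes averaged 8.06 log2 against 6.86 to 7.51 on the others. Its ERCC spikes had a median of 4.72, within the 4.66 to 5.01 of the others. On each of the 10 arrays the ERCC median lay under the background median, so it cannot show whether this array is in place. Background probes had a median of 4.98 log2 on the MDSL control array and 5.41 to 5.43 on the others.

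The series compared OR21-treated with untreated cells. Across the 4 lines, DAZL, an RNA-binding protein of germ cell development, rose with OR21 by 7.28 ± 1.63 log2 (SD, n = 4 lines) (adjusted p = 0.0271), which is a minimum size because its controls were at or under background. The interferon-inducible gene IFI6 rose by 4.09 ± 0.79 log2 (adjusted p = 0.0271), and ID2, an inhibitor of helix-loop-helix transcription factors, rose by 3.30 ± 0.42 (adjusted p = 0.0215). DCAF4L1 rose by 4.10 ± 0.28 log2 (adjusted p = 0.00452). IL23R, a subunit of the interleukin-23 receptor, rose by 2.46 ± 0.44 (adjusted p = 0.0434), CYRIA by 2.41 ± 0.23 and RNF4BP by 2.28 ± 0.26 (adjusted p = 0.0271 for both). Each of these 7 genes was higher in 4 of 4 lines.

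These 7 genes were the only ones of 17687 past the threshold in limma, and 0 fell. At an unadjusted p under 0.05 there were 3372 genes. The count was 1 without HL60, 2 without K562, 0 without SKM1 (2181 at an unadjusted p under 0.05) and 5 without MDSL, of which 2 were among the 7. It was 1 with no cell line block.

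Median centring moved the median difference of all genes from -0.05 to -0.22 log2 in HL60, from -0.02 to -0.17 in SKM1, from 0.00 to -0.14 in K562, from -0.02 to -0.18 in the AZA resistant and from -0.07 to -0.22 in the OR21 resistant derivative. Scaling to the spikes moved it to -0.82 in HL60 and 0.11 in K562. By size alone, 75 genes were at least 2-fold higher and 40 at least 2-fold lower in all 4 lines. With each array centred on its median the split was 62 higher and 65 lower. Without HL60, whose treated array stood apart in the hybridisation spikes, 107 genes were higher and 52 lower in the other 3 lines. The counts were 157 and 80 without MDSL, 106 and 73 without SKM1, and 288 and 158 without K562.

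Among the genes higher in all lines but not past the test, GCNA, a germ cell nuclear protein, differed by 5.66 ± 2.41 log2 (SD, n = 4 lines, adjusted p = 0.102) and the meiotic chromosome protein HORMAD1 by 4.74 ± 1.49 (adjusted p = 0.0822). PNMA5 differed by 4.06 ± 1.13 (adjusted p = 0.0662) and YPEL3 by 4.08 ± 1.95 (adjusted p = 0.104). The cancer-testis genes CT45A8 and CT45A9 had identical values, a mean difference of 4.09 ± 3.25, and CT45A6 had 4.00 ± 2.94. These copies are nearly identical in sequence, so their probe sets cannot be taken as separate genes. CT45A8 was at 12.01 log2 in control K562 and at 3.86 to 4.75 in the controls of the other 3 lines. Its controls in these 3 lines, and those of DAZL and DCAF4L1 in all 4, were at or under the background median of their array, so these differences are limited by background and are minimum sizes. The same holds in part for IL23R, with such a control in 2 lines, and for RNF4BP, GCNA, PNMA5 and CT45A6, with 1 line each.

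The genes lower in all 4 lines held the nucleolar and ribosome assembly genes NOP16 (-2.22 ± 1.17 log2), NPM3 (-2.14 ± 1.26), GPATCH4 (-2.02 ± 1.04) and WDR3 (-1.88 ± 1.28). The amino acid transporter SLC38A5 differed by -2.56 ± 2.16, the kinase MATK by -2.24 ± 0.45 and the potassium channel KCNQ5 by -2.17 ± 0.79. SLC25A10, a mitochondrial dicarboxylate carrier, differed by -2.02 ± 0.70, the mitochondrial DNA helicase TWNK by -1.92 ± 0.92 and the purine synthesis enzyme PFAS by -1.91 ± 0.43. None of these 10 passed the test, with adjusted p from 0.0662 for MATK to 0.163 for SLC38A5. Except for MATK and PFAS, the largest of the 4 differences was in HL60, whose treated array stood apart in the hybridisation spikes. Without HL60 the mean difference was -1.50 for SLC38A5 and -1.24 for WDR3.

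**Figure D1:**
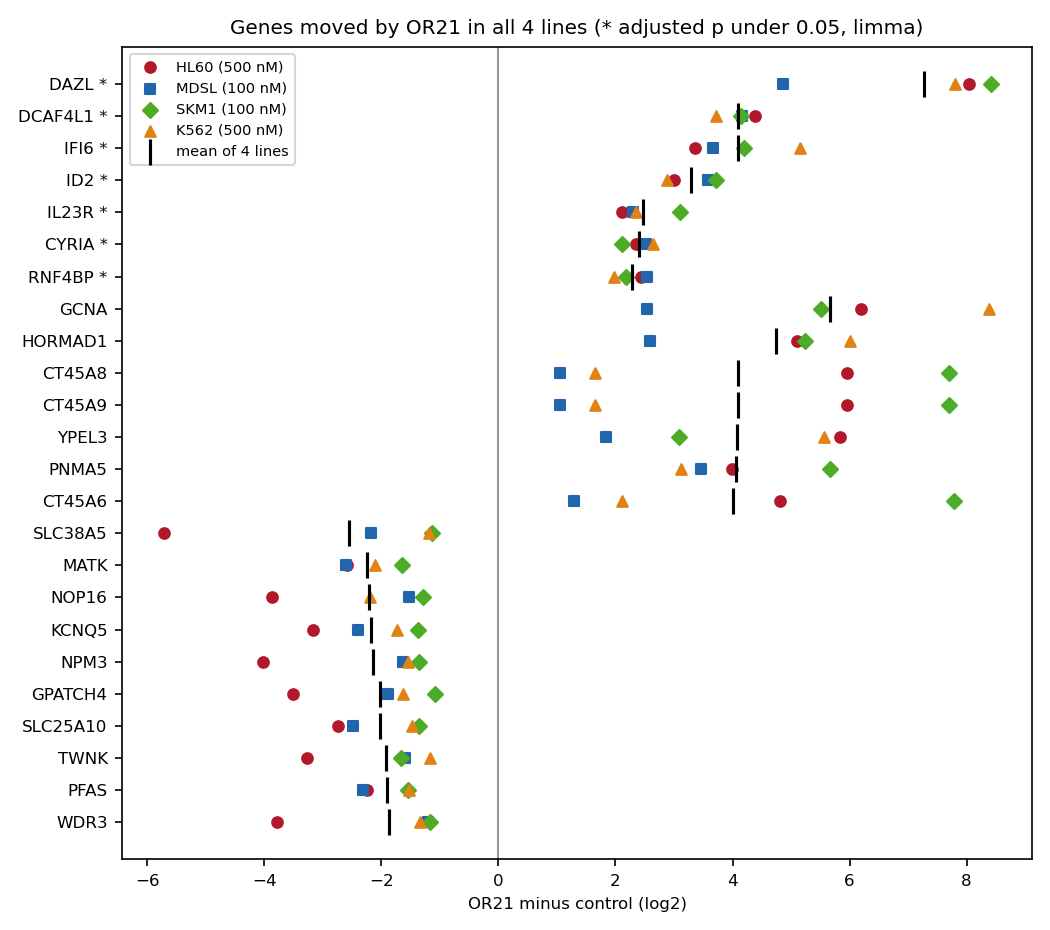
The horizontal axis gives OR21 minus control in log2 units and the vertical axis lists the 24 genes named over the 4 lines, with 1 symbol per line and a black bar for the mean of 4 lines. The 7 genes with an asterisk passed adjusted p = 0.05 in limma, and DAZL ranged from 4.86 in MDSL to 8.41 in SKM1.

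Genes fixed in advance as interferon-stimulated were higher on average in 36 of 36 measured members, with a median of 1.30 log2 over the 4 lines. After IFI6, the smallest p values were those of the transcription factor IRF9 at 3.48 ± 1.07 log2 (SD, n = 4 lines, adjusted p = 0.0822), PARP14 at 1.79 ± 0.44 and IFI27 at 3.17 ± 1.42. Over all genes 1 member passed, and 23 did so adjusted over the list alone. The list median was 0.85 in HL60, 1.84 in MDSL, 1.62 in SKM1 and 0.47 in K562. Camera with the preset correlation called the list (adjusted p = 4.57e-17), and the call was lost at adjusted p = 0.398 with an estimated correlation.

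Germline genes had a median of 0.43 log2 over the 4 lines and cancer-testis antigens 0.47. In the germline list 28 of 34 members were higher on average, 1 passed over all genes and 7 did so adjusted over the list alone. Besides DAZL and HORMAD1 these included MAEL, which acts in transposon silencing in germ cells, at 3.60 ± 2.31 log2 (SD, n = 4 lines), and STK31 at 1.17 ± 0.64. Of 33 cancer-testis antigens, 23 were higher on average, 0 passed over all genes and 9 did so adjusted over the list alone. PAGE5 stood at 2.41 ± 1.20, PAGE2B at 2.64 ± 1.53, PAGE2 at 2.66 ± 1.66 and MAGEA1 at 0.99 ± 0.53. MDSL had the lowest medians of both lists, 0.11 and 0.09. Camera called both lists with the preset correlation, at adjusted p = 1.04e-05 and adjusted p = 0.000348. With an estimated correlation they had adjusted p = 0.398 and adjusted p = 0.419.

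Myelomonocytic differentiation genes were higher on average in 28 of 30 members, with a median of 1.46 log2. The NADPH oxidase subunit NCF1 differed by 2.96 ± 1.71 log2 (SD, n = 4 lines), the calcium-binding S100A9 by 2.83 ± 1.75, the macrophage protein CD68 by 2.11 ± 1.16 and the lysosomal protease CTSD by 1.63 ± 0.75. In this list 0 genes passed over all genes and 11 did so adjusted over the list alone. Its median was 2.44 in HL60, where the treated array stood apart in the hybridisation spikes, 0.69 in MDSL, 1.17 in SKM1 and 0.25 in K562. NF-kB and inflammatory genes were higher on average in 17 of 19 members, with a median of 1.15. The smallest p was that of TNFAIP3 at 1.92 ± 0.47, the 1 member past the threshold adjusted over the list alone. CCL2, a monocyte chemoattractant, was higher by 6.54 to 8.13 log2 in HL60, MDSL and SKM1 and differed by -1.10 in K562, where the list median was 0.00 and turned to -0.11 under quantile normalization. Camera with the preset correlation gave adjusted p = 1.24e-09 and adjusted p = 7.30e-06 for these lists, and both had adjusted p = 0.398 with an estimated correlation.

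DNA replication genes were lower on average in 26 of 26 members, with a median of -1.10 log2. GINS1, a subunit of the replicative helicase, differed by -1.66 ± 0.74 log2 (SD, n = 4 lines), MCM10 by -1.32 ± 0.61, the sliding clamp PCNA by -1.26 ± 0.55 and the polymerase subunit POLA1 by -1.12 ± 0.28. Over all genes 0 passed, and 17 did so adjusted over the list alone. The list median was -1.77 in MDSL, -1.32 in SKM1, -1.18 in HL60 and -0.03 in K562, where quantile normalization gave 0.01. Fanconi and homologous recombination genes were lower on average in 14 of 14 members, 4 of them past the threshold adjusted over the list alone. XRCC2 stood at -1.57 ± 0.82 and RAD54L at -1.23 ± 0.60. The Fanconi list had medians of -0.87 in HL60, -0.94 in MDSL and -1.15 in SKM1 and 0.20 in K562. Mitosis genes had medians of -1.64 in MDSL and -0.81 in SKM1, but 0.32 in K562 and 0.11 in HL60, the last turning to -0.06 under median centring. Cholesterol synthesis genes had medians of -1.39 in HL60, -0.24 in MDSL and -1.13 in SKM1 and 0.06 in K562, the last turning to -0.09 under median centring. By the mean of the 4 lines, 21 of 24 mitosis genes and 13 of 15 cholesterol genes were lower, with 0 members of either past the threshold, BIRC5 at -0.98 ± 0.57 and DHCR7, an enzyme of the last steps of cholesterol synthesis, at -1.65 ± 1.32. Camera with the preset correlation called these 4 lists, at adjusted p = 8.54e-13, adjusted p = 7.48e-06, adjusted p = 0.00180 and adjusted p = 0.000679. With an estimated correlation they had adjusted p = 0.398, adjusted p = 0.398, adjusted p = 0.499 and adjusted p = 0.419.

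Metallothionein genes, which bind metal ions, were higher on average in 8 of 9 members, 6 of them past the threshold adjusted over the list alone. MT1F stood at 1.62 ± 1.20 log2 (SD, n = 4 lines) and MT2A at 1.71 ± 1.62. The metallothionein medians were 1.64 in HL60, 0.60 in MDSL, 2.37 in K562 and 0.01 in SKM1. The SKM1 median turned to -0.02 under quantile normalization and -0.13 under median centring. Erythroid genes were higher on average in 19 of 20 members, 4 of them higher in all 4 lines. The erythroid list had medians of 1.60 in MDSL, 1.21 in K562 and -0.01 in HL60 and in SKM1. HBA1, an alpha globin gene, was higher by 5.75 in MDSL and the erythroid factor GATA1 by 3.80 in SKM1. Megakaryocyte and mast cell genes were higher on average in 16 of 17 members, with the platelet integrin ITGA2B at 1.75 ± 1.56. The medians of this list were 1.47 in MDSL, 0.17 in HL60, 0.40 in SKM1 and 0.28 in K562. Among apoptosis regulators 17 of 21 were higher on average. The anti-apoptotic gene BCL2 differed by -1.83 ± 0.58 and was the 1 member past the threshold adjusted over the list alone. p53 target genes were higher on average in 19 of 25 members, with medians of 0.33 in HL60, 0.27 in MDSL and 0.34 in K562. The p53 median of 0.03 in SKM1 turned to -0.11 under median centring. The cell cycle inhibitor CDKN1A differed by 3.21 ± 1.42 (adjusted p = 0.102), with 4.21 in HL60, 4.03 in MDSL, 3.48 in SKM1 and 1.14 in K562. TP53INP1 stood at 2.20 ± 0.93, whereas TRIAP1 and AEN stood at -1.72 ± 0.48 and -1.13 ± 0.43. Nucleic acid sensing genes, with EIF2AK2 at 1.16 ± 0.83, were higher on average in 11 of 17 members. T and NK lymphocyte markers, with GNLY at 2.51 ± 2.52, were higher on average in 13 of 15. In K562 the medians of the apoptosis, nucleic acid sensing and T and NK lists were -0.02, -0.01 and -0.04.

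Camera with the preset correlation called these 7 lists too, at adjusted p from 0.000398 for metallothioneins to 0.0398 for nucleic acid sensing. Each was lost, at adjusted p = 0.398 with an estimated correlation for 5 of them and adjusted p = 0.418 with an estimated correlation for metallothioneins and apoptosis regulators. Of the 31 lists, camera called 16, 12 up and 4 down, with the preset correlation, 0 with an estimated correlation, and the directional test of fry called 0. Fry's test of change in either direction had adjusted p = 0.0255 for interferon-stimulated genes and for p53 targets and called no other list. Swapping treated and control within some lines, in the 7 other possible ways, also gave 6 to 13 calls with the preset correlation.

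DNA methylation genes were not called as a list (adjusted p = 0.390), and their members went both ways. The maintenance methyltransferase DNMT1 differed by -1.13 ± 0.60 log2 (SD, n = 4 lines, adjusted p = 0.125) and its partner UHRF1 by -1.18 ± 0.64, while DNMT3A, a de novo methyltransferase, differed by 1.66 ± 0.85 (adjusted p = 0.117). DNMT3B went from -1.02 in K562 to 1.34 in HL60. In the nucleoside list (adjusted p = 0.113), the dNTP hydrolase SAMHD1 differed by 1.20 ± 0.46 (adjusted p = 0.115) and was higher in 4 of 4 lines. CAD and UMPS, which make pyrimidines, stood at -1.38 ± 0.79 and -1.31 ± 0.61. CDA, cytidine deaminase, differed by 2.94 in HL60, 2.30 in MDSL, 1.13 in SKM1 and -0.08 in K562 (adjusted p = 0.173). DCK, which phosphorylates deoxycytidine, had a mean difference of 0.00 ± 0.45, SLC29A1 of 0.26 ± 0.92 and UCK1 of -0.15 ± 0.19. CDKN2B differed by 0.19 ± 0.39.

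The other lists were not called at the preset correlation. Genes reported as silenced by methylation in myeloid neoplasms had a median of 0.19 log2 (adjusted p = 0.134), with DAPK1 at 1.23 ± 0.67. Imprinted genes also had a median of 0.19 (adjusted p = 0.134), with CDKN1C at 1.23 ± 0.65 and INPP5F at 1.44 ± 0.80. MYC, in the stem and progenitor list (adjusted p = 0.242), differed by -4.62 in HL60, -2.48 in MDSL, -2.47 in SKM1 and -0.76 in K562. The stress response list had adjusted p = 0.150, NRF2 targets adjusted p = 0.102, class I presentation genes adjusted p = 0.169, class II genes adjusted p = 0.370, primary granule genes adjusted p = 0.932, with a negative median and a positive direction by fry, and housekeeping genes adjusted p = 0.225. Markers of fibroblasts and endothelium and of epithelium had adjusted p = 0.170, B lymphocyte markers adjusted p = 0.370 and neural markers adjusted p = 0.390. Among these markers PECAM1 was higher by 4.58 in HL60 and KRT18 by 6.00 in HL60.

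**Figure D2:**
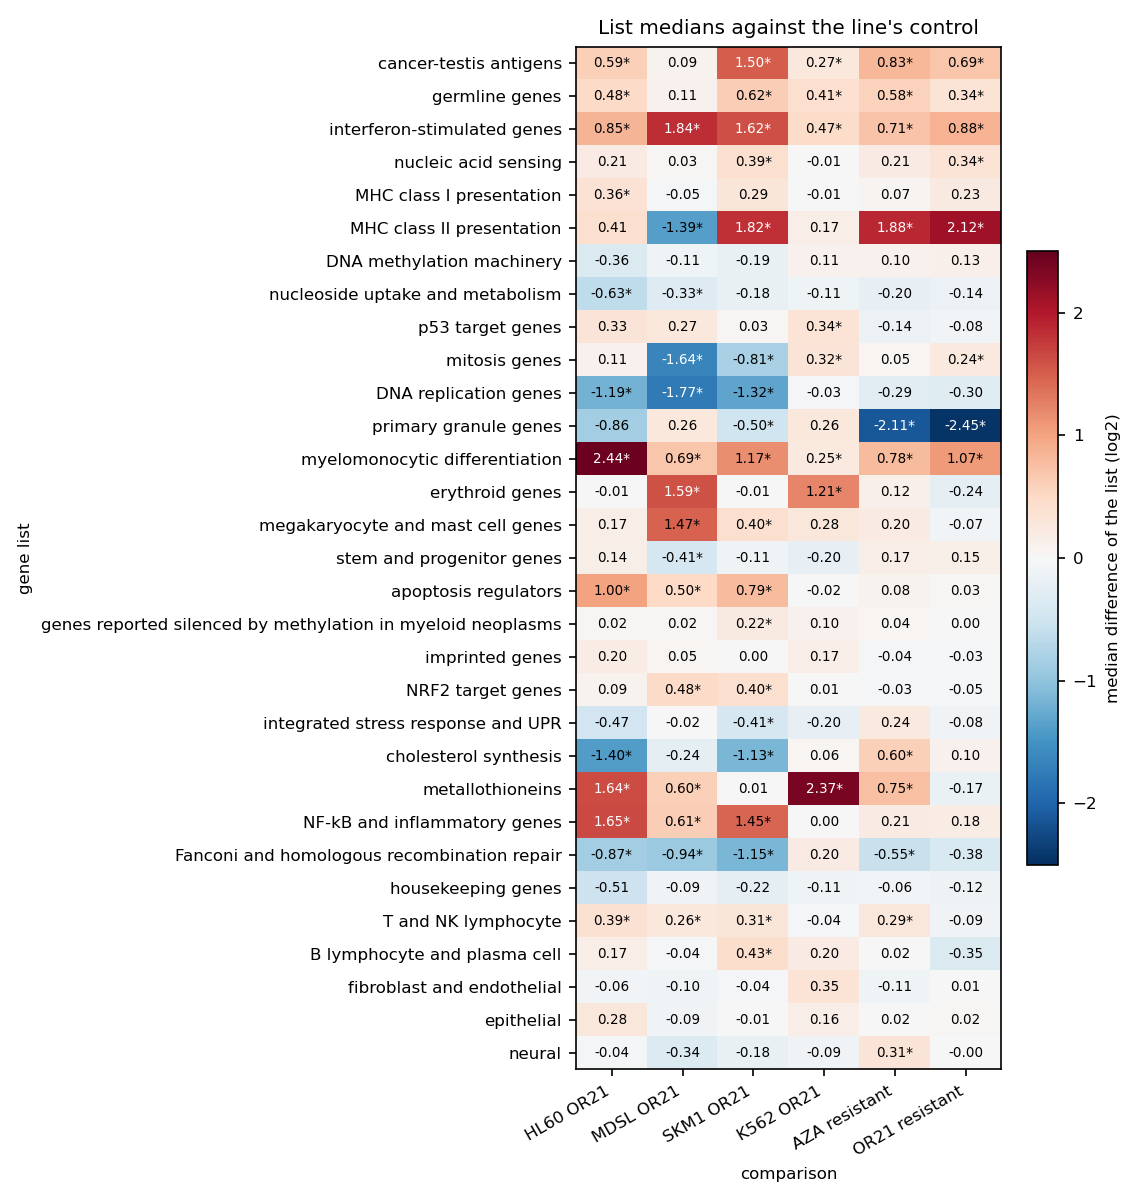
Rows are the 31 gene lists and columns are 6 comparisons with the control of the same line, with colour and number giving the list's median difference in log2 units. Asterisks mark medians outside the central 95% of 10000 random lists matched on mean expression, such as 2.44 for myelomonocytic genes in HL60, and 40 of 217 medians over 7 comparisons, none larger than 0.14 in size, change sign under quantile normalization or median centring.

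The lines were also compared 1 by 1, without replicates. The control was at or under its array's background median for 6 of the 10 genes named as higher in HL60, 4 in MDSL, 10 in SKM1 and 7 in K562, so those differences are minimum sizes. In HL60 at 500 nM the matrix protease MMP9 was higher by 9.31 log2, the tetraspanin CD9 by 8.52, the matrix protein TGFBI by 8.50, FAM9C by 8.38, DAZL by 8.04, VNN2 by 7.65, S100A12 by 7.28, the formyl peptide receptor FPR1 by 6.99 and the endotoxin co-receptor CD14 by 6.97. IER3 was higher by 7.25. The lowest differences were SLC38A5 (-5.72), the neuropeptide GAL (-5.58), MYC (-4.62), LAMP5 (-4.52), ABCB10 (-4.40), GALNT14 (-4.38), BDH1 (-4.34), the spermidine synthase SRM (-4.15), the fatty acid desaturase SCD (-4.13) and NPM3 (-4.03). In HL60 1802 genes were at least 2-fold higher and 1962 lower. The split was 1481 and 2574 with each array centred on its median, and 792 and 6810 with each array scaled to its hybridisation spikes, in which the treated array stood apart.

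In MDSL at 100 nM the steroid synthesis genes CYP11A1, which cleaves the cholesterol side chain, and STAR, which carries cholesterol into mitochondria, were higher by 10.14 and 6.52 log2. CILP was higher by 8.11, KIAA0040 by 7.71, C4BPA by 6.62, CCL2 by 6.54, PGA5 by 6.53, COL14A1 by 6.21, the interferon-inducible IFI44L by 6.17 and NPY1R by 5.97. MPO, myeloperoxidase of the primary granules, was higher by 4.49 in MDSL and differed by -1.09 to -0.95 in the other 3 lines. Lower genes included the histones H4C9 (-3.63), H3C8 (-3.55), H2AC8 (-3.04) and H1-5 (-2.94), the receptor FLT3 (-3.51), CDCA7 (-3.43), NREP (-3.31), TMEM97 (-3.28), SOX4 (-3.23) and NRG4 (-2.99). MDSL had 1170 genes at least 2-fold higher and 864 lower. Class II presentation genes had a median of -1.38 in MDSL and 1.82 in SKM1.

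In SKM1 at 100 nM, GAGE12G was higher by 8.43 log2, DAZL by 8.41, CT45A5 by 8.38, CT45A3 by 8.30, CT45A1 by 8.16, CCL2 by 8.13, CT45A7 by 7.91, CT45A6 by 7.79 and CT45A8 and CT45A9 by 7.70 each. The members of the CT45A family, and of the GAGE family, are nearly identical in sequence. The lower genes were FLT3 (-4.04), TBC1D30 (-3.59), VIT (-3.40), GPM6B (-3.25), the granule protease PRTN3 (-2.75), DPYSL3 (-2.68), DHCR7 (-2.67), MANEAL (-2.63), PLPPR3 (-2.57) and TPD52L1 (-2.53). SKM1 had 1255 genes at least 2-fold higher and 791 lower, or 1001 and 1210 with each array centred on its median.

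In K562 at 500 nM the histone gene H2BC14 was higher by 10.33 log2, GCNA by 8.38, DAZL by 7.80, carbonic anhydrase CA1 by 7.09, LXN by 6.32, ALAS2, which starts haem synthesis in red cells, by 6.13, TDRD12 by 6.12, HORMAD1 by 6.01, ALOX12 by 5.77 and XAGE1B by 5.67. The transporter SLCO2B1 was lower (-4.39), as were ARHGDIB (-2.94), NTS (-2.54), C3AR1 (-2.52), LPCAT1 (-2.49), FOSL1 (-2.31), SLC10A4 (-2.27), MRTO4 (-2.26), NOP16 (-2.19) and CAVIN2 (-2.18). K562 had 893 genes at least 2-fold higher and 682 lower. The split was 682 and 1046 with each array centred on its median and 1171 and 458 scaled to the spikes. Over genes, which are not independent replicates, responses correlated most between HL60 and SKM1 (r = 0.548) and least between MDSL and K562 (r = 0.206).

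**Figure D3:**
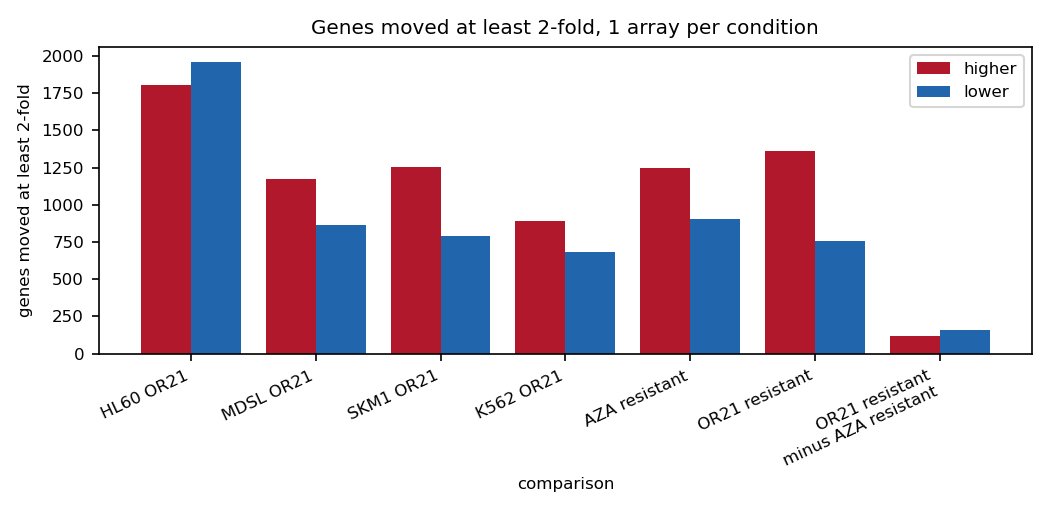
Bars give the number of genes at least 2-fold higher (red) or lower (blue), from 0, for each of 7 comparisons on the horizontal axis, with 1 array per condition. HL60 has 1802 higher and 1962 lower genes, and the 2 resistant derivatives differ from each other in 120 and 157.

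HL60 and K562 received 500 nM, and MDSL and SKM1, which derive from myelodysplastic disease, received 100 nM. Dose therefore cannot be told apart from line and disease of origin. H2BC14 differed most, with 6.55 log2 in HL60 and 10.33 in K562 against -2.90 in MDSL and -1.51 in SKM1. KIT, a stem cell factor receptor, was at 0.85 and 2.74 in these lines and was negative in both others, at -2.38 in SKM1, H1-5 at 0.26 and 3.10 against -2.94 and -1.58, and SCIN at 0.77 and 4.70 against 0.23 and -2.21. In the other direction stood CYP11A1 (-0.44 and 1.16 against 10.14 and 5.78), COL14A1 (0.47 and -0.21 against 6.21 and 5.89), and the pepsinogens PGA5 (-0.08 and 0.16 against 6.53 and 4.58) and PGA3 (-0.06 and -0.67 against 5.82 and 4.20). In limma 0 genes passed the interaction test, with 968 at an unadjusted p under 0.05 and the lowest of these 8 adjusted p values at 0.314 for COL14A1. By list, camera with the preset correlation called 7 differences, among them mitosis genes with a median difference of 1.43 and interferon-stimulated genes with -0.81. Both had adjusted p = 0.543 with an estimated correlation, and 0 lists were called with it.

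The resistant derivatives were compared with parental HL60 controls. Of the 10 genes named as higher, the parental control was at or under background for 7 in the AZA resistant and 8 in the OR21 resistant derivative, so those differences are minimum sizes. In the AZA resistant derivative XAGE1B was higher by 9.63 log2, the near-identical family members GAGE13, GAGE12G and GAGE1 by 8.28, 7.91 and 7.89, MAEL by 7.59, PNMA5 by 7.39, DPEP3 by 7.24 and HORMAD1 by 7.15. H2BC14 was higher by 8.74 and PPP1R27 by 7.60. Among the lowest were CKMT1A, a mitochondrial creatine kinase, at -6.15, its near-identical copy CKMT1B at -5.72, SERPINB10 at -5.86, the protease inhibitor CST7 at -5.38 and MS4A3 at -5.37. MLC1 (-4.81), GAL (-4.70), GXYLT2 (-4.41), the transcription factor NFATC2 (-4.36) and MYO10 (-4.36) followed. In all 1246 genes were at least 2-fold higher and 903 lower, or 1014 and 1377 with each array centred on its median.

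In the OR21 resistant derivative XAGE1B was higher by 9.71 log2, FAM9C by 9.51, the matrix proteoglycan VCAN by 7.62, PNMA5 by 7.57, GAGE12G by 7.43, HORMAD1 by 7.22, GAGE13 by 7.21, DPEP3 by 7.19, GAGE1 by 7.15 and CTCFL, a testis paralogue of CTCF, by 6.93. The lower genes were SERPINB10 (-7.83), CST7 (-6.12), CKMT1A (-5.96), CKMT1B (-5.68), PTPRCAP (-5.39), VIT (-5.19), GXYLT2 (-4.88), MS4A3 (-4.84), SLPI (-4.83) and MLC1 (-4.44). In this derivative 1361 genes were at least 2-fold higher and 756 lower, or 1139 and 1149 with each array centred on its median.

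By list, class II presentation genes had medians of 1.88 log2 in the AZA resistant and 2.12 in the OR21 resistant derivative, at the 100th percentile of matched random lists in each. HLA-DRA was higher by 6.45 and 6.52 and HLA-DPA1 by 5.74 and 6.29. Primary granule genes had medians of -2.11 and -2.45, at the 0 percentile in each, with PRTN3 at -4.15 and -3.88, while CLC in that list stood at 2.82 and 2.59. Interferon-stimulated genes had medians of 0.71 and 0.88, also at the 100th percentile, with MX2 at 4.45 and 4.78 and MX1 at 3.11 and 3.32. Myelomonocytic genes had medians of 0.78 and 1.07, with VCAN at 5.67 and 7.62, although CEBPE, a granulocyte transcription factor, stood at -3.07 and -3.86. Cancer-testis antigens had medians of 0.83 and 0.69 and germline genes of 0.58 and 0.34. Of the nucleoside genes, the ectonucleotidase NT5E stood at 4.74 and 4.53, SAMHD1 at 1.63 and 1.97, the transporter SLC28A3 at -1.90 and -1.79, DCK at -0.42 and -0.72 and CDA at -0.78 and 0.02. DNMT3B stood at 1.79 and 2.25, DNMT3A at 1.38 and 1.52 and DNMT1 at 0.07 and 0.05. The epithelial marker KRT18 stood at 3.31 and 3.75.

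**Figure D4:**
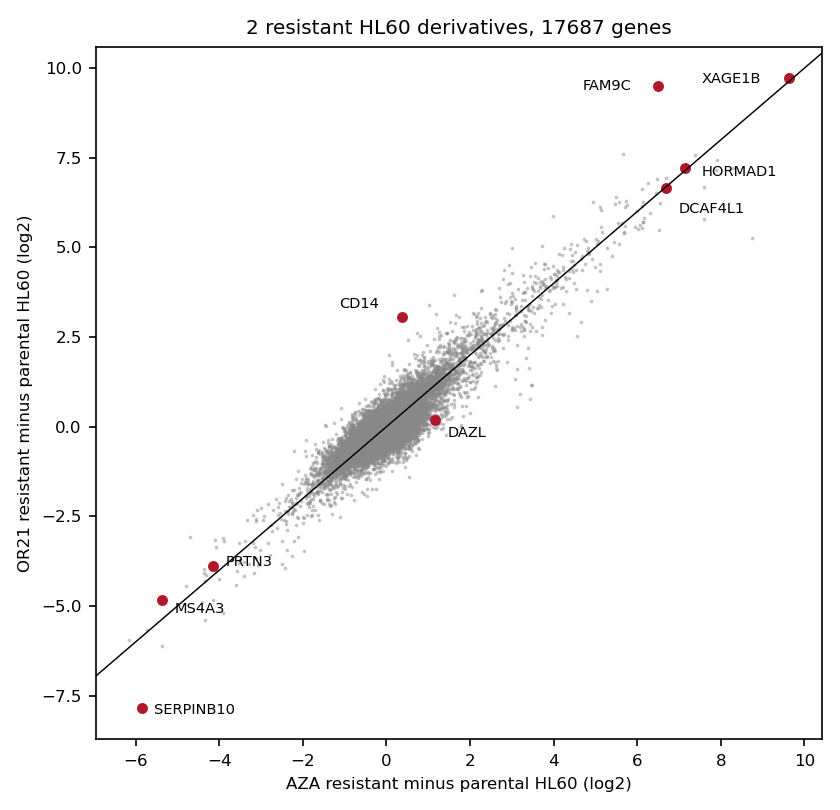
Each grey point is 1 of 17687 genes, with the AZA resistant (horizontal) and OR21 resistant (vertical) derivative minus parental HL60 in log2 units, and the line marks equal values. Named genes are in red, and most lie near the line, with FAM9C and CD14 (0.37 and 3.06) above it and SERPINB10 (-5.86 and -7.83) below.

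The derivatives shared 1030 genes at least 2-fold higher and 531 lower than parental cells, and 0 genes went opposite ways. Opposite ways would need a 4-fold difference between the derivatives, which only 11 genes had, so the 0 carries little information. Independent lists of these sizes would share 95.9 and 38.6. With each array centred on its median the shared counts were 848 and 795. Across genes the correlation was 0.903 and the covariance 0.665. Both comparisons used the same HL60 control array. Simulated noise of equal spread, with a shared control and no change, gave a correlation of 0.501, a covariance of 0.0718 and 7.45 shared higher genes. Equal spread by itself sets a correlation near this value, and the spread was taken from the difference between the derivatives. Part of the excess may come from the shared control. The response of HL60 to OR21 correlated with the AZA resistant difference at 0.433 (covariance 0.385) and with the OR21 resistant difference at 0.406 (covariance 0.370). These comparisons share the HL60 control too. Both correlations lie below the simulated 0.501 and both covariances above the simulated 0.0718. The simulated spread was measured on neither the control nor the OR21-treated array, so these values do not decide whether the differences are related.

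Compared directly with the AZA resistant derivative, the OR21 resistant one had a median difference of 0.04 log2 in the myelomonocytic list. Among single genes, FAM9C was higher by 3.01 log2, CD14 by 2.69, LPAR3 by 2.39, osteopontin (SPP1) by 2.05, VSIG4 by 1.98, SIGLEC9 by 1.96, VCAN by 1.95, the scavenger receptor CD36 by 1.90, the kinase SGK1 by 1.90 and GPNMB by 1.88. Lower genes were the histones H2BC14 (-3.47), H2BC8 (-2.58) and H2AC8 (-2.29), HHLA2 (-2.66), DLX1 (-2.32), TSPAN2 (-2.29), TUBA3D (-2.04), SERPINB10 (-1.98), CEACAM6 (-1.95) and TDRD6 (-1.80). In all 120 genes were at least 2-fold higher and 157 lower. Metallothioneins had a median of -0.77 and cholesterol synthesis genes of -0.32, both at the 0 percentile of matched random lists.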

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

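The tests of the HL60 OR21 array as the source of the HL60 changes and the counts of swaps for genes were chosen after the results were seen, as was the scaling to spikes. The tests of a brightness trend, of the parental array and of swaps for lists were set down before.

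In 74 groups of 4 lines or 10 arrays, 6 held a value whose gap to the nearest other, over the range of the group, passed Dixon's 95% critical value. Chance gives about 1 such value in 20 groups, or 3.7 in 74, and the groups share arrays. NPM3 differed by -4.027 log2 in HL60 and by -1.64 to -1.36 in the other lines, and WDR3 by -3.789 in HL60 and by -1.33 to -1.18 in the others. MPO was higher by 4.491 in MDSL and differed by -1.09 to -0.95 in the others. The median of fibroblast and endothelial markers was 0.3512 in K562 and -0.10 to -0.04 in the others. The mean of the hybridisation spikes was 11.71 log2 on the array of OR21-treated HL60 and 10.85 to 11.10 on the other arrays. Background probes had a median of 4.98 on the MDSL control array and 5.41 to 5.43 on the others.

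HL60 moved the most genes, 3764 by at least 2-fold, and its treated array was the one apart in the hybridisation spikes. Of these genes, 84.5% had the sign of the mean of the other 3 lines, and 74.7%, 83.8% and 70.4% had the sign in MDSL, SKM1 and K562. This argues against changes of random sign on this array as the whole source. An array that enlarged the differences would keep their signs, so the share does not say why HL60 moved the most genes. With a smooth trend of the difference on brightness removed, 3698 genes were past 2-fold in HL60, and the counts in MDSL, SKM1 and K562 went from 2034, 2046 and 1575 to 2028, 2044 and 1540. The trend was small in each line, which argues against a trend of this kind as the whole source. A different load of target or of spikes could still have scaled this array, and scaling to the spikes gave 7602 genes, 792 higher and 6810 lower. Line and dose also stay open as untested biological explanations.

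The resistant derivatives shared 1561 genes past 2-fold in 1 direction, and both were set against the same parental array. Against the array of OR21-treated HL60, 693 of them, or 44.4%, were also past 2-fold in the same direction in both derivatives, against 6.73% of other genes moved in any 1 given direction, as the mean of the 2 directions. This argues against the parental array alone as the source for that part of the genes. The median HL60 response to OR21 was 0.78 log2 for genes higher in both derivatives and -0.89 for genes lower in both. A parental array out of place would also give such a shift, so it stays open for the rest of the genes. Resistance, and time in culture, stay open as biological explanations and were not tested.

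Between the lines at 500 nM and at 100 nM, 7 lists differed in the test of the difference by camera with the preset correlation. The median differences were -0.8107 for interferon-stimulated genes, 1.428 for mitosis genes, 1.897 for metallothioneins, -0.9004 for megakaryocyte and mast cell genes and 0.4886 for epithelial markers, each with adjusted p = 0.543 with an estimated correlation. They were 0.9608 for DNA replication genes and 0.8255 for Fanconi and homologous recombination genes, each with adjusted p = 0.945 with an estimated correlation. Among the named genes, H2BC14 (10.65), KIT (3.985), H1-5 (3.942) and PGA3 (-5.376) went opposite ways in the pairs of lines, and the limma test of the difference did not pass for any of them. The genes were named because both lines at either dose lay above both at the other, so that separation was set by the choice. Some of the opposite signs rest on small differences in HL60. Dose, line and disease of origin differ together here.

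Among 3761 probe sets outside the table of genes, 7 were at least 2-fold higher and 8 at least 2-fold lower in all 4 lines, with at most 1 in any of the 7 other swaps of treated and control within lines.

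Swapping treated and control within lines gives 8 splits that part all 4 pairs, too few for a share under 0.05. The real split called 7 genes and the highest other 0, so 1 of 8 called as many. It moved 115 genes at least 2-fold the same way in all lines and the highest other 14, and it called 16 lists and the highest other 13, again 1 of 8 each. Among splits that part 2 pairs, the form setting OR21 against control the same way in HL60 and SKM1 called 59 genes. MDSL and K562 each had both arrays on the same side there, so it is the real comparison in HL60 and SKM1 alone. With HL60 and SKM1 parted in opposite ways, 0 genes were called. The responses of these lines correlated at r = 0.548 over genes, and a link between that and the 59 genes was not tested.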

How the results depend on the processing

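Scaling to spikes, and leaving out lines in the count of genes moved 2-fold in all 4 lines, were chosen after seeing the data. The cause of each difference below was not tested, except that fewer lines leave fewer arrays for the fit and fewer conditions to meet, and that a larger fold size passes fewer genes. The 7 genes past the threshold became 1 with no cell line block and 0 to 5 with 1 line left out (0 without SKM1, 1 without HL60, 2 without K562, 5 without MDSL), and stayed 6 or 7 under the other settings. The 16 lists became 0 by camera with the estimated correlation and 0 by the directional test of fry. At 1.5-fold and at 4-fold the counts were 7001 and 1085 in HL60, 5193 and 437 in MDSL, 5174 and 390 in SKM1, 4664 and 198 in K562, 5018 and 560 in the AZA resistant and 4999 and 636 in the OR21 resistant derivative, 1937 and 11 between the derivatives, 3441 and 484 in their overlap, and 559 and 15 in all 4 lines. Scaling to the spikes gave 7602 in HL60. The 115 genes moved 2-fold in all 4 lines became 159 without HL60 to 446 without K562, with 237 without MDSL and 179 without SKM1. Mean differences that changed sign were those of DNMT3B (0.184 without MDSL and 0.3312 without K562, range from -0.4569 without HL60), DCK (0.01757 under quantile normalization, -0.2244 without MDSL to 0.1103 without HL60) and MPO (-1.025 without MDSL, up to 0.8342 without SKM1). Of the other values of named genes over the 4 lines, 311 kept direction and side of the threshold, 31 kept direction and lost the call, and 1 gained it. The values of named genes in single comparisons (280) and in the dose comparison (56) kept their direction. Of the values of called lists, 76 kept the call and 36 lost it with direction kept. Background probes had medians of 4.98 to 5.43 log2, against gene medians of 6.63 to 7.05, so differences among dim genes are limited by background.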

Other observations

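The families below, of the mitochondrial ribosome, ribosome assembly, RNA polymerase I and mitochondrial complex I, were chosen by symbol prefix after the data were seen, and their tests were chosen after the result was seen. Of 74 mitochondrial ribosomal protein genes, 73 had a negative mean and 56 were lower in all 4 lines, with medians of -1.35 log2 in HL60, -0.41 in MDSL, -0.62 in SKM1 and -0.62 in K562. Of 24 UTP, NOP and RRP genes, which act in ribosome assembly, 23 had a negative mean, with medians of -1.65 in HL60, -0.59 in MDSL, -0.53 in SKM1 and -0.87 in K562. RNA polymerase I genes, 8 of 8 negative, had medians of -2.19, -1.09, -0.83 and -0.95 in the same order. Complex I genes had a median of -1.01 in HL60, whose treated array stood apart in the hybridisation spikes, and of -0.20, -0.22 and -0.27 in MDSL, SKM1 and K562, where they lay at percentiles 10.5, 5.36 and 3.37 of matched random lists. Cytosolic ribosomal protein genes, 51 of 69 with a negative mean, had medians of -0.03 in HL60, -0.32 in MDSL, -0.09 in SKM1 and 0.13 in K562, the last of which turned to -0.01 under median centring. In the AZA and OR21 resistant derivatives the medians were -0.48 and -0.47 for the mitochondrial ribosome, -0.42 and -0.08 for ribosome assembly, -0.44 and -0.20 for RNA polymerase I, -0.64 and -0.60 for complex I and -0.22 and -0.24 for cytosolic ribosomal proteins. Against matched random lists, ribosome assembly and RNA polymerase I lay at percentiles 49.3 and 28.9 in the OR21 resistant derivative. Camera with the preset correlation called the first 4 of these families, with adjusted p = 2.77e-22 for the mitochondrial ribosome. With an estimated correlation 0 were called, at adjusted p = 0.283 for the mitochondrial ribosome, ribosome assembly and RNA polymerase I and adjusted p = 0.409 for complex I.

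The array of OR21-treated HL60 does not enter the differences of the other 3 lines, whose highest median for the mitochondrial ribosome was -0.4055, so it is not the source there. Random lists of like brightness were not as low, with this family at the 0 percentile in all 4 lines, which argues against brightness alone. The family was picked because it was low, so neither value says how rare such a family is. The signs of the 4 medians held under quantile normalization and median centring. No biological explanation was tested.

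Replication-dependent histone genes, 61 in number, had medians of 0.13 log2 in HL60, which turned to -0.04 under median centring, -1.14 in MDSL, -0.93 in SKM1 and -0.34 in K562. This family was also chosen by symbol prefix after the data were seen. Camera with the preset correlation called it as lower (adjusted p = 6.53e-05), and the call was lost at adjusted p = 0.535 with an estimated correlation. Of the 75 genes at least 2-fold higher in all 4 lines, 11 lie on the X chromosome, or 14.7% against 3.99% of all genes, and 4 of the 11 are CT45A copies. Of the 75, 26 (34.7%) were also at least 2-fold higher in both resistant derivatives and 3 at least 2-fold lower in both, against 5.82% and 3.00% of all genes. Of the 40 genes lower in all 4 lines, 6 were also lower in both and 1 was higher. The derivatives share the HL60 control with these sets. Of the 107 genes at least 2-fold higher in MDSL, SKM1 and K562, which do not use that control, 28 (26.2%) were higher in both derivatives and 3 lower, and of the 52 lower genes 6 (11.5%) were lower in both and 2 higher. These counts without HL60 were added after the data were seen. DAZL, chosen here after its values were seen, stood at 1.17 in the AZA resistant and 0.18 in the OR21 resistant derivative.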
